A study of Drosophila melanogaster with 288 samples.

How the data were processed

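RNA-seq was measured in 288 libraries of Drosophila melanogaster S2R+ cells, a cell line derived from embryos that takes up long double-stranded RNA (dsRNA) from the medium and degrades the matching transcript. Per the labels' protocols, cells at 100000 per ml in medium with 10% serum were plated on 2.7 µg of dsRNA per well and collected after 24, 48 or 72 h (days 1, 2 and 3). Each day was 1 plate of 96 wells, with the same dsRNA at the same position on every plate, so plate and day cannot be separated. Strand-specific libraries were made from 1 µg of total RNA by poly(A) selection with 13 cycles of PCR and read from a single end over 76 bp, per the labels.

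The groups came from the sample titles. Of the 46 targets, 44 had 2 dsRNAs and 2 (alphaCOP and Trf) had 1, which makes 90 dsRNAs. In addition, 1 well per plate held dsRNA against thread, and 5 wells per plate were controls with dsRNA against LacZ, dsRNA against GFP or no dsRNA. The labels used here do not say which of the 5 is which. The replicates of a target are its dsRNAs, called dsRNA 1 and dsRNA 2. No 2 count tables were identical (0 pairs).

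The deposited counts are whole numbers of reads per gene, made by the authors with TopHat2 2.0.10 for alignment and HTSeq for counting after base calling with CASAVA 1.8.2 on genome build BDGP6, per the submitters' processing notes. The HTSeq version and strand setting are not given in the sources used here. The count tables list 17409 genes, 96 ERCC spike-in RNAs added during library making and 5 summary lines. Reads outside any annotated gene made up a median of 69.6% of the entries of a count table (66.1% to 75.5%) and ambiguous reads 0.536%, and neither entered library sizes or tests. The deposited FPKM values (fragments scaled by gene length and depth) are the authors' Cufflinks 2.2.1 output, per the submitters' processing notes, and served in 1 alternative on the scale of log2(FPKM + 1), which understates changes of low genes.

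Gene symbols were taken from the Ensembl annotation of BDGP6, which held 17172 of the 17409 identifiers. Its loci had the same start and end as those of the deposited FPKM tables for 16825 of 17099 genes, and coordinates are printed as in those tables. The counts matched these positions in only part of the genome. Of 66 housekeeping genes on chromosome arm 2L and on the first 4.4 Mb of 3L, 63 (95.5%) had at least 1000 counts over the 288 libraries, against 45 of 219 (20.5%) on 2R, 3R, X and the rest of 3L. Examples are eEF2 on 2L with 6709640 counts and RpL8 on 3L with 2630830, against 11 for Act5C on X, 21 for RpL3 on 3R and 1 for RpS3 on 3R. Tests were therefore restricted, after this was seen, to 4092 genes (3377 on 2L, 678 on the first 4.4 Mb of 3L and 37 of the mitochondrion), which held a median of 61.0% of the counts assigned to genes. The transcripts of 36 targets and of thread lie outside this part and were not measured.

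Counts of the 3 days were summed per well, because the days of 1 dsRNA share its position and off-targets, and each target was compared with the 5 control wells by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. All 96 wells shared 1 estimate of the spread, libraries were scaled by TMM, and genes with at least 1 count per 1000000 (CPM) in at least 2 wells were kept (2586 genes). A second fit of the 288 single libraries (3173 genes) gave the contrasts within each day, the difference of a response between day 3 and day 1 and the control wells over time. P-values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05, and "adjusted p" means this. Errors of log2 fold changes are standard errors (SE), taken as the log2 fold change over the square root of the F statistic, and levels are mean CPM ± SD. For targets with 1 well the spread came from the other wells. Groups with 0 counts are compared through a floor of 3 counts over the group, and ratios from 1 to 3 counts carry exact 95% intervals; these cover counting error only. Changed genes of a target are those past the threshold against the control wells.

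Gene lists were fixed before the data were examined, as were the groups, tests, filters, partner pairs and the alternatives except those named below. Of 31 lists, 19 with at least 5 measured members were tested in 46 targets and thread with camera of limma 3.58.1 (preset correlation 0.01, 893 tests adjusted together, the target's own gene left out), and again with an estimated correlation. The tested lists were DNA replication and S phase, G2/M and mitosis, fatty acid synthesis, hypoxia and glycolysis, ecdysone response, immune response, hemocyte, muscle, actin, neuronal, germline and epithelial genes, EGFR response, DNA damage, secretory pathway, unfolded protein response, ribosomal proteins, insulin and TOR signalling, and histones. The lists of E2f2-repressed genes, heat shock, metal response, JNK response, circadian clock, Hippo pathway, apoptosis, oxidative stress, Notch response, JAK/STAT response, RNAi and transposon-derived genes had fewer measured members and are given gene by gene.

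The rule for named genes was fixed too. It takes every measured target in its own knockdown. For the 10 targets with the most changed genes it takes the 3 genes that rose most and the 3 that fell most, with at least 5 CPM in the higher group and on 1 side of the same-day control mean, taken over pooled wells, in every library. For other targets with at least 10 changed genes it takes the first of each by the same rule, and for thread and the control wells over time 10 in each direction. In place of the side of the control mean, it asks of the control wells that days 1 and 3 do not overlap. It adds up to 4 members of lists past the threshold and the 10 genes changed in the most knockdowns. Target genes may be named wherever they passed the threshold. Genes outside the rule are said to be so.

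Agreement of both dsRNAs of a target and the similarity of known partner factors were measured as correlations across genes, which are not independent replicates, with one-sided permutation tests of 100000 resamples. Alternatives were DESeq2 1.42.0 (its size factors and its Wald test), spike-in scaling, no filter on low counts, means of the per-day contrasts, limma voom with and without the well as a block, plate row as a covariate, and FPKM. Others were libraries under 1000000 gene counts left out, the compared days alone, and leaving out each control well or each dsRNA. Added after the data were seen were the use of all genes of the count tables, leaving out libraries under 100000 used counts and leaving out wells A2, C2 and E2 of day 3, next to wells whose target transcript was low in them. Spike-in scaling moved the median log2 fold change of all genes by over 0.1 in 30 of the 46 targets and thread, from -2.43 in thread to 0.43 in ap, and DESeq2 size factors by at most 0.096. Changes are relative to the TMM scale, on which the median gene stays near 0.

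The tests were checked on simulated counts drawn from the real means and library sizes, with 200 genes changed. These were drawn from genes with at least 5 CPM in the control wells, and both wells of a target got the same change. Recovery of lower genes, or of changes that differ between dsRNAs, was not tested. Single libraries were drawn with the spread of the 3-day sums and without an effect of the well. Recovery and false calls at the real spread of single libraries were thus not tested either. For kay (2451 genes) edgeR recovered 96% and 94% of genes lowered by 2 and 1 log2 units and 96% and 100% of those raised by 1 and 2, with 3 false calls. For thread (1 well, 2451 genes) it recovered 82% and 66% of genes lowered by 2 and 1 and 62% and 92% of those raised by 1 and 2, with 5 false calls. For SREBP at day 3 (2586 genes) the shares were 94%, 76%, 82% and 96% in the same order of folds, and for its difference between days 88%, 60%, 66% and 88%. For the control wells between day 3 and day 1 they were 92%, 92%, 94% and 100%, with 8 false calls. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.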

Results

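Poly(A) RNA of S2R+ cells was counted per gene after dsRNA-mediated knockdown of 46 targets, nearly all of them transcription factors, with the question of which genes respond to the loss of each. The libraries came from 3 plates of 96 wells collected at days 1, 2 and 3. Each of 44 targets had 2 dsRNAs and thus 6 libraries, alphaCOP and Trf had 1 dsRNA and 3 libraries each, the cell-death control thread had 3 libraries, and the control wells gave 15. A target over the 3 days is compared as n = 2 wells (1 for alphaCOP, Trf and thread) against n = 5 control wells. Nothing in the labels says that wells are separate cultures, so each p-value measures the spread between these samples, which may be technical.

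The libraries held a median of 977646 counts on genes, from 1164 to 2680297, and a median of 601202, from 727 to 1640794, on the 4092 genes that were used. These lie on chromosome arm 2L, on the start of 3L and on the mitochondrial genome (build BDGP6), because most housekeeping genes elsewhere had few counts. Per day the median used counts were 660873, 493523 and 640485.5. A total of 15 libraries held fewer than 100000 used counts, among them the control wells 3 and 4 of day 1 with 3476 and 2791. Of 149 genes named by the rule, 67 overlap another annotated gene and 18 of these do so on the same strand. Among the latter are Oseg4, NimC4, CG7916, squ, stai, Glut1, Pcyt1, Arpc2, robo2 and Pxn, and CycE, CG10383, Hsp83, qtc, gNacalpha, zormin, CG42324, Btk, capt and Arpc5 overlap a gene on the opposite strand. Counts of overlapping genes and of the near-identical histone copies are uncertain, since the strand setting of the counting is not known.

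The own transcript of 10 targets was measurable, and it was called lower in 7 of their knockdowns. With FPKM 4 of these calls were made and with spike-in scaling 1, while all 7 kept their direction in both. Mondo (FBgn0032940, 2L 21286078 to 21310050), partner of the sugar-responsive factor Mlx, fell by 1.60 ± 0.09 (log2 fold change ± SE) from 984.6 ± 135.1 CPM (mean ± SD) to 322.4 ± 11.7, lower in 6 of 6 libraries (edgeR, adjusted p = 9.82e-25). The ETS repressor aop (FBgn0000097, 2L 2156484 to 2178754) fell by 1.46 ± 0.09 to 36.6% of the control level, in 6 of 6 libraries (edgeR, adjusted p = 3.36e-23). The coatomer subunit alphaCOP (FBgn0025725, 3L 1641066 to 1645199) fell by 1.95 ± 0.21 to 26.1% in 3 of 3 libraries (edgeR, adjusted p = 6.4e-09), and tsh (FBgn0003866) by 1.32 ± 0.09 to 39.7% in 6 of 6 (edgeR, adjusted p = 1.6e-20). Smaller declines were those of E2f2 (FBgn0024371) to 58.1%, in 5 of 6 libraries (-0.79 ± 0.12, edgeR, adjusted p = 5.12e-06), and of vri (FBgn0016076) to 57.9%, in 6 of 6 (-0.76 ± 0.13, edgeR, adjusted p = 0.000377). Mrtf (FBgn0052296) fell to 60.8%, in 5 of 6 (-0.72 ± 0.11, edgeR, adjusted p = 3.68e-05). These 3 calls were lost when a single dsRNA remained: E2f2 without dsRNA 2 (-0.50), Mrtf without dsRNA 2 (-0.30), and vri without dsRNA 1 (-0.72) or dsRNA 2 (-0.78), so that 4 of the 7 remained without dsRNA 2.

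The other 3 measurable transcripts were not called lower over the 3 days. Trf (FBgn0010287), a TBP-related factor, was higher by 1.27 ± 0.18 in its own knockdown (edgeR, adjusted p = 3.37e-06). It stood at 274% and 263% of the control level at days 1 and 2 and 26.6% at day 3, higher in 2 of 3 libraries that held 141, 36 and 5 counts. The bHLH factor da (FBgn0267821) stood at 213%, 97.0% and 112% of the control on days 1 to 3 with dsRNA 1 and at 17.9%, 29.5% and 20.5% with dsRNA 2. The test of both together was not passed (-0.29 ± 0.22, 4 of 6 libraries lower, edgeR, adjusted p = 1). Within days, da was called higher at day 1 (0.56, edgeR, adjusted p = 0.0234) and lower at days 2 (-0.67, 0.00173) and 3 (-0.69, 0.000257). Without dsRNA 2 it was higher over the 3 days (0.49). The nuclear receptor Hr39 (FBgn0261239) stood at 96.0%, 94.9% and 75.8% with dsRNA 1 and at 207%, 173% and 126% with dsRNA 2 (0.21 ± 0.11, 3 of 6 libraries higher, edgeR, adjusted p = 1), and at -0.21 without dsRNA 2. Adjusted over the list alone the same 7 were lower and Trf higher, with 0.188 for da and 0.0831 for Hr39. In all, 45 of 54 libraries were below the level of the pooled same-day control wells. E2f2, Mondo, da, vri, Mrtf and aop overlap genes on the opposite strand. The transcripts of the other 36 targets and of thread lie outside the used part, so whether those knockdowns worked was not measured here.

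**Figure D1:**
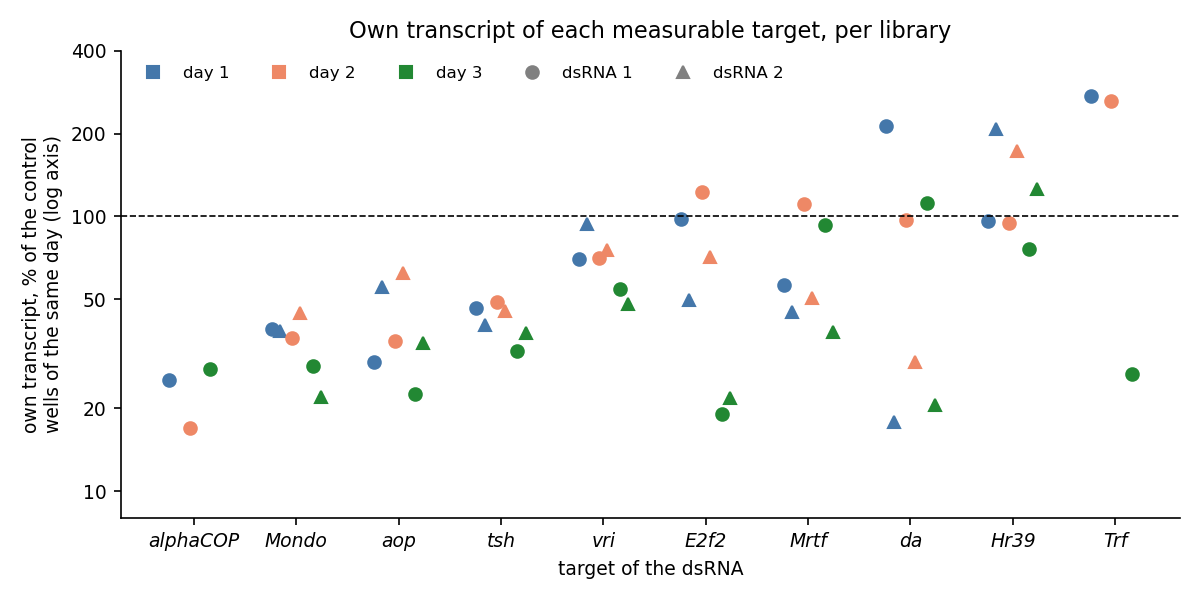
Own transcript of each of 10 targets in percent of the pooled same-day control wells (log axis), with 1 point per library, colour for the day and marker for the dsRNA. Libraries of Mondo lie between 22.1% and 44.3%, while Trf, da with dsRNA 1 and Hr39 with dsRNA 2 lie above 200% at day 1.

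Over 3 days the AP-1 subunit kay changed the most genes of the 46 targets, 520 (241 higher, 279 lower). It was followed by the E2F partner Dp with 286 (192 higher, 94 lower), the ETS factor pnt with 253 (112 higher, 141 lower), the hypoxia factor sima with 147 (73 higher, 74 lower) and the zinc-finger homeodomain factor zfh1 with 127 (99 higher, 28 lower). Next came Jra with 113 (20 higher, 93 lower), Myb with 97 (38 and 59), mip120 with 96 (65 and 31), srp with 57 (23 and 34) and SREBP with 50 (22 and 28). These 10 held 1746 (92.2%) of the 1894 calls of the 46 targets (975 higher, 919 lower; edgeR, 2586 genes tested), which fell on 1021 genes, 515 of them changed in 1 target only. Of the other targets, 5 had between 15 and 46 changed genes (ttk, E2f2, pnr, Trl and dwg), 15 had 1 to 9 and 16 had none. The order depends on the scale: FPKM gave 431 for pnt against 268 for kay, and spike-in scaling 130 for Dp against 41 for kay. Comparisons of 2 control wells with the other 3 gave 0 or 1 changed genes in each of the 10 possible splits (47 to 256 genes at an unadjusted p under 0.05), and simulated unchanged wells gave 1 call over 44 targets.

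The counts changed when a dsRNA was left out, which leaves a target with 1 well. Fewer calls can come from that loss of power alone, and no comparison at equal power was made. With dsRNA 2 left out the sum was 883, and 2 instead of 6 targets had 100 or more changed genes. Per target the counts then were 300 for kay, 48 for pnt, 25 for sima, 16 for zfh1, 56 for Jra, 62 for Myb, 37 for mip120, 6 for srp and 12 for SREBP. With dsRNA 1 left out they were 110 for Dp, 19 for sima, 39 for Jra, 55 for Myb, 32 for mip120 and 91 for srp, and without control well 4 sima had 97. Under scaling to the spike-ins the share of higher calls moved from 51.5% to 80.6% over all targets, from 67.1% to 100% for Dp and from 46.3% to 24.4% for kay, with far fewer calls. It moved from 49.7% to 33.3% for sima, from 78.0% to 91.7% for zfh1, from 17.7% to 40.0% for Jra. For the rest it moved from 39.2% to 78.6% in Myb, from 67.7% to 100% in mip120, from 40.4% to 25.0% in srp and from 44% to 0% in SREBP. DESeq2 size factors moved that of Dp to 81.1%.

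**Figure D2:**
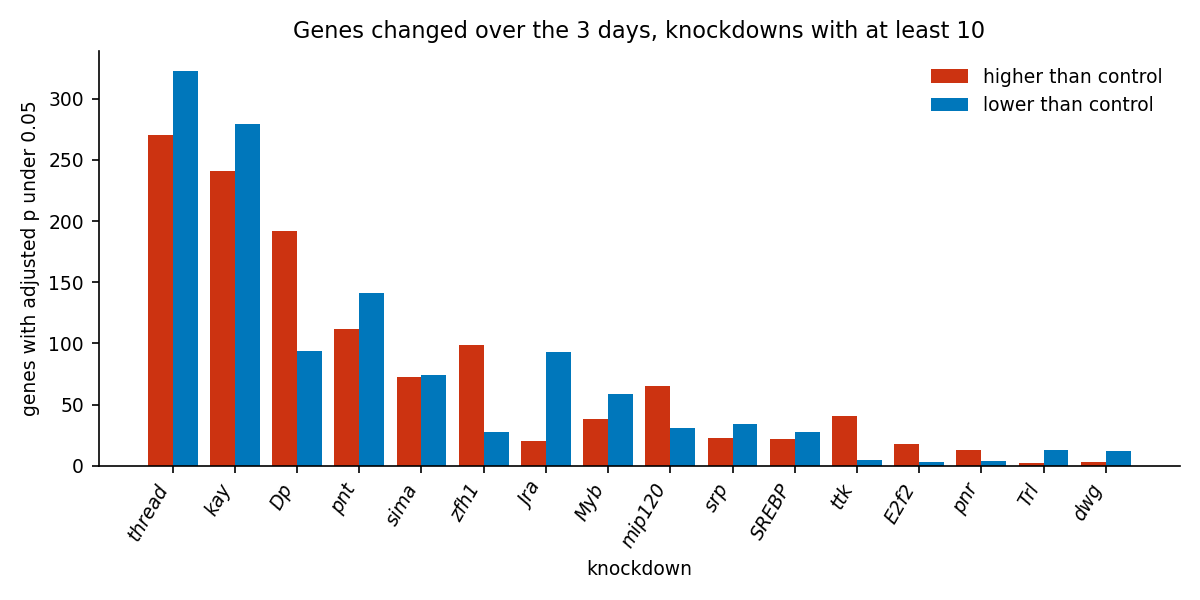
Number of changed genes higher (left of each pair of bars) and lower (right) than in the control wells over 3 days, for thread and the 15 targets with the most. Thread (270 higher, 323 lower) and kay (241 higher, 279 lower) had the longest bars, and under spike-in scaling the share of higher calls of thread fell from 45.5% to 0.1%.

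The 16 targets with 0 changed genes over 3 days by edgeR were CrebA, CrebB, Eip74EF, Hr39, MTF-1, Mef2, Pdp1, ap, cwo, exd, grau, h, maf-S, sd, tgo and usp. Each had 58 to 170 genes at an unadjusted p under 0.05. DESeq2 gave 4 calls over the 16 (3 for CrebB, 1 for Pdp1), and limma voom with the well as a random block gave 51, at most 9 (CrebB), with none for exd and h. Days 1, 2 and 3 alone gave 46, 46 and 70 calls over the 16 (edgeR), at most 12 (grau), 6 (MTF-1) and 20 (CrebB). A further 9 targets changed 1 gene, among them alphaCOP, Mrtf, Trf, aop, tsh and vri, whose own transcripts are described above.

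Kay and Jra are the Fos and Jun subunits of AP-1, and most of the genes that changed in Jra changed in the same direction in kay. CG18557 (FBgn0031470, 2L 2844601 to 2845734) fell from 90.7 ± 28.2 CPM to 5.64 ± 3.65 in kay (-3.76 ± 0.58, 6 of 6 libraries, edgeR, adjusted p = 1.6e-06). In Jra it fell to 12.1 ± 2.31 (-2.75 ± 0.53, 6 of 6, edgeR, adjusted p = 0.00036). Kah (FBgn0035144, 3L 582824 to 589274), a Snail-family zinc-finger factor, fell from 192.2 ± 26.1 CPM to 33.3 ± 4.88 in kay (-2.49 ± 0.24, 6 of 6, edgeR, adjusted p = 6.77e-12). Jra knockdown lowered it to 63.7 ± 4.20 (-1.59 ± 0.22, 5 of 6, edgeR, adjusted p = 6.55e-07). The kinase Btk rose from 231.5 ± 16.5 CPM to 421.7 ± 20.2 in kay (0.87 ± 0.09, 6 of 6, edgeR, adjusted p = 5.46e-13) and by 0.51 ± 0.09 in Jra (6 of 6, edgeR, adjusted p = 5.67e-05). In kay CG33509 rose from 2.79 ± 1.06 to 34.8 ± 8.16 CPM (3.68 ± 0.42, 6 of 6, edgeR, adjusted p = 3.13e-11). The next risers were CG4629 (2.12) and lncRNA:CR45717 (1.799), each in 6 of 6 libraries. CG7916, with 2 counts against 48, was 11.1-fold lower (counting interval 2.90 to 94.1), and Idgf1, with 3 counts against 45, was 6.92-fold lower (2.22 to 34.8), a call lost without dsRNA 1 (-2.91). The formin capu fell by 1.01 ± 0.11 in kay (6 of 6, edgeR, adjusted p = 9.97e-12).

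In Jra the lipid carrier Apoltp (1.33 ± 0.25), fbp (1.11 ± 0.22) and the peroxidasin Pxn (0.67 ± 0.16) rose most among genes higher in 6 of 6 libraries (edgeR, adjusted p = 0.000268, 0.000201 and 0.00567), and all 3 calls were lost without dsRNA 1 (1.09, 0.92 and 0.46). The growth factor gene Pvf3 (-1.49 ± 0.32) and CG32982 (-1.45 ± 0.39) fell in 6 of 6 libraries (edgeR, adjusted p = 0.00128 and 0.0174). Their calls and that of CG18557 were lost without either dsRNA, at -1.29 and -1.84 for Pvf3, -1.47 and -1.36 for CG32982, and -2.60 and -3.01 for CG18557 (without dsRNA 1 and 2). The subunits shared 94 changed genes, 11 higher and 83 lower in both, where independent lists of these sizes would share 1.86 and 10.0 (Fisher's exact test, adjusted p = 8.05e-49). With the control wells split between them they shared 53 or 72, and without the day-3 wells A2, C2 and E2 78. Simulated unchanged wells shared 0, but with 1 call over 44 targets they had almost none to share. Simulated changes of 1 log2 unit in kay, in genes with at least 5 CPM, were recovered at 94% when lowered and 96% when raised.

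**Figure D3:**
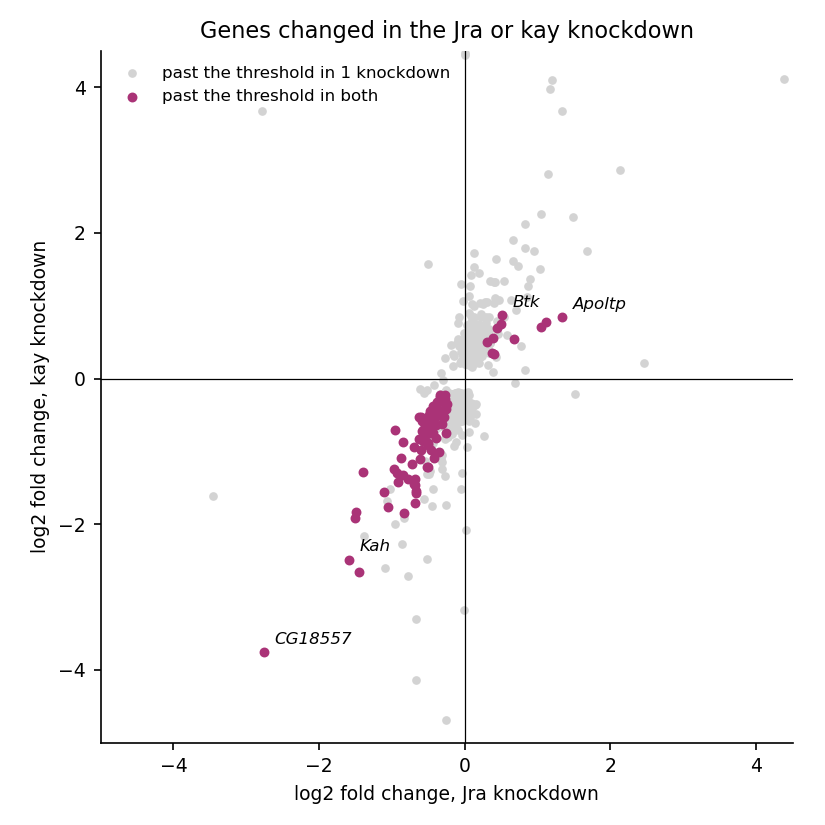
Log2 fold change over 3 days in the kay knockdown (vertical) against the Jra knockdown (horizontal), 1 point per gene changed in either, 539 in all. The 94 genes changed in both lie in the lower left (83) and upper right (11).

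The cell-cycle factors Dp, E2f2, mip120, Myb and E2f1 belong to the E2F and dREAM complexes. In Dp the cilium transport gene Oseg4 rose from 1.82 ± 1.23 to 47.7 ± 17.7 CPM (4.59 ± 0.47, 6 of 6 libraries, edgeR, adjusted p = 7.3e-12). CG4213 rose from 4.44 ± 3.04 to 98.9 ± 19.1 (4.43 ± 0.32, 6 of 6, edgeR, adjusted p = 3.22e-19). CG31636, with 27 counts against 3, was 21.2-fold higher (6.53 to 109). Cyclin E, CycE (FBgn0010382, 2L 15727581 to 15748150), fell from 279.2 ± 17.2 to 133.8 ± 7.16 CPM (-1.05 ± 0.13, 6 of 6, edgeR, adjusted p = 3.72e-09). The replication gene Psf1 fell from 74.2 ± 12.3 to 39.0 ± 0.967 (-0.96 ± 0.20, 6 of 6, edgeR, adjusted p = 0.000302). E2f2 itself fell by 0.52 ± 0.12 in Dp (6 of 6, edgeR, adjusted p = 0.00103, lost without dsRNA 2 at -0.32 and without the day-3 wells A2, C2 and E2 at -0.22). At day 3 it fell by 1.14 in Dp, where well C2 lies next to a well of E2f2 dsRNA, and stood at -0.30 without these 3 wells. In Myb it fell by 0.48 ± 0.11 (6 of 6, edgeR, adjusted p = 0.00227, lost without dsRNA 2 at -0.40). His2A:CG33817 fell by 2.00 ± 0.67 in Dp (6 of 6, edgeR, adjusted p = 0.0393), a call lost without control well 2 (-1.95), 3 (-1.94) or 4 (-1.92) and without dsRNA 1 (-1.46) or 2 (-2.88).

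Knockdown of mip120, a DNA-binding subunit of dREAM, raised qtc from 1.62 ± 1.19 to 41.6 ± 6.53 CPM (4.72 ± 0.48, 6 of 6 libraries, edgeR, adjusted p = 1.57e-11). CG13084 rose from 14.0 ± 6.26 to 120.4 ± 18.5 (3.27 ± 0.20, 6 of 6, edgeR, adjusted p = 9.65e-23), and CG32313 rose as well (2.92 ± 0.48, 6 of 6, edgeR, adjusted p = 9.62e-06). The knockdown lowered squ (-0.83 ± 0.13), stai (-0.80 ± 0.15) and Reph (-0.68 ± 0.19), each in 6 of 6 libraries (edgeR, adjusted p = 2.65e-06, 0.000462 and 0.0258). The call of stai was lost without dsRNA 1 (-0.77), and that of Reph without dsRNA 1 (-0.76), dsRNA 2 (-0.58) or control well 5 (-0.63). Knockdown of Myb lowered the mitotic kinase adaptor Cks30A (FBgn0010314, 2L 9330763 to 9331981) from 287.6 ± 31.1 to 97.7 ± 4.65 CPM (-1.59 ± 0.11, 6 of 6, edgeR, adjusted p = 8.36e-19). IFT52 fell by 2.41 ± 0.29 and CG14036 by 1.78 ± 0.23. The same knockdown raised Fam92 from 2.56 ± 2.60 to 33.4 ± 8.34 CPM (4.08 ± 0.40, 6 of 6, edgeR, adjusted p = 4.41e-13). The next were dao, which rose by 3.83 ± 0.39 and gNacalpha by 3.25 ± 0.40, all in 6 of 6 libraries.

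The targets of these complexes overlapped in part. E2f2 had 21 changed genes (18 higher, 3 lower), and 17 of the 20 apart from the target genes were shared with Dp (16 higher, 1 lower; 1.34 and 0.07 under independence; Fisher's exact test, adjusted p = 6.63e-14; 11 or 14 with split controls, 16 without the day-3 wells A2, C2 and E2). With mip120 E2f2 shared 10, all higher in both (0.45 under independence; adjusted p = 7.42e-10; 7 or 8 with split controls). Myb and mip120 shared 28, of which 12 were higher in both, 7 lower in both and 9 opposite (0.96 and 0.71; adjusted p = 1.36e-18; with split controls 14 the same way in either split and 9 or 6 opposite). The 5 shared by E2f2 and Myb all moved in opposite directions (3 or 4 opposite with split controls, 3 shared without the day-3 wells A2, C2 and E2). Fisher's exact test, ignoring direction, gave adjusted p = 0.000738. Simulated unchanged wells shared 0 in each pair but had almost none to share. E2f1 changed 5 genes, 1 of them shared with Dp (adjusted p = 0.444), and 0 without the day-3 wells A2, C2 and E2 (edgeR). At day 3 it held 37112 scaled counts (Dp 1326210), so few calls need not mean little effect. Of the E2f2-repressed genes fixed beforehand, pyx and vas were measured. In 6 of 6 libraries each, the channel gene pyx rose in Dp (2.52, edgeR, adjusted p = 6.23e-20), E2f2 (1.90, 7.87e-13) and mip120 (1.41, 4.67e-09) and fell in Myb (-1.18, 0.000329). The germline helicase vas rose in Dp (3.04, 6 of 6, edgeR, adjusted p = 0.000131) and E2f2 (2.76, 4 of 6, 0.00607), was not called in mip120 (1.97, 5 of 6, 0.0609, and 0.0024 adjusted over the list alone) and stayed level in Myb (-0.05, 1). That made 6 of 8 values past the threshold, and 7 adjusted over the list alone.

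The ETS activator pnt acts downstream of the EGF receptor, and of 10 EGFR response genes 4 fell in its knockdown (camera, adjusted p = 2.82e-05, adjusted p = 0.119 with an estimated correlation). The Ras inhibitor gene sty (FBgn0014388, 3L 3401153 to 3424935) fell from 12040 to 3195 CPM (-1.91 ± 0.11, 6 of 6 libraries, edgeR, adjusted p = 1.17e-25). The gene kek1 fell from 1624 to 822.3 (-0.98 ± 0.10, 6 of 6, edgeR, adjusted p = 1.21e-11) and aop from 2332 ± 107.5 to 1319 ± 126.2 (-0.82 ± 0.08, 6 of 6, edgeR, adjusted p = 3.58e-12). The ligand gene spi fell by 0.32 (6 of 6, edgeR, adjusted p = 0.00216), a call lost without dsRNA 1 (-0.27) or 2 (-0.35). The growth factor gene Idgf3 rose from 390.7 ± 20.9 to 916.3 ± 132.2 CPM (1.24 ± 0.14, 6 of 6, edgeR, adjusted p = 4.84e-09). The axon guidance receptor robo2 rose from 216.5 ± 18.8 to 433.2 ± 90.4 (0.98 ± 0.14, 6 of 6, edgeR, adjusted p = 3.22e-07), and Reg-2 from 20.3 ± 6.20 to 62.4 ± 26.5 (1.52 ± 0.27, 6 of 6, edgeR, adjusted p = 2.16e-05, lost without dsRNA 2 at 1.02). CG15382 (-2.41), CG15818 (-2.39) and lncRNA:CR45820 (-1.99) fell most among genes lower in 6 of 6 libraries (edgeR, adjusted p = 0.00953, 0.00216 and 0.0231). The first pair was lost without dsRNA 2 (-1.87 and -1.71) and the lncRNA without dsRNA 1 (-2.88), dsRNA 2 (-1.46) or control well 5 (-1.85). Hr39 fell by 0.50 ± 0.13 in pnt (5 of 6, edgeR, adjusted p = 0.00513), but was higher with FPKM (0.53). CG15382 lies opposite aop, so reads of one can be counted for the other. Knockdown of aop, the repressor paired with pnt on shared sites, changed no measured gene but its own in the sums over 3 days (edgeR). In days 1, 2 and 3 alone it changed 8, 12 and 6 genes, and 14 at day 3 without wells A2, C2 and E2.

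Sima is the hypoxia-inducible factor and tgo its partner. In sima fok (FBgn0263773, 2L 20079270 to 20085070) fell from 1140.0 ± 300.8 to 37.2 ± 27.8 CPM (-5.05 ± 0.65, 6 of 6 libraries, edgeR, adjusted p = 2.54e-07). The mitochondrial assembly gene Sirup (FBgn0031971, 2L 7998869 to 7999676) fell from 2792 ± 544.0 to 505.5 ± 19.2 (-2.47 ± 0.30, 6 of 6, edgeR, adjusted p = 6.25e-08). The clock gene tim, with 3 counts in the target, was 14.9-fold lower (4.95 to 73.5). Cyp28d1 rose from 21.5 ± 12.8 to 52.1 ± 8.65 CPM (1.55 ± 0.33, 6 of 6, edgeR, adjusted p = 0.00231), and lncRNA:CR45717 (1.63 ± 0.44) and Ggamma30A (1.53 ± 0.45) rose in 6 of 6 libraries (edgeR, adjusted p = 0.0149 and 0.0286). The calls of tim (-3.62 and -3.66), Cyp28d1 (1.71 and 1.37), lncRNA:CR45717 (1.79 and 1.44) and Ggamma30A (1.55 and 1.51) were lost without dsRNA 1 and without dsRNA 2, that of Ggamma30A also without control well 1 (1.39) or 4 (1.49). Fok and Sirup lie opposite neb and Wwox. Tgo changed 0 genes by edgeR over 3 days, with 99 at an unadjusted p under 0.05, 0 by DESeq2 and 4 by voom. At day 3 alone it changed 3, and 8 without wells A2, C2 and E2. Among the 3 were fok (-1.05, 2 of 2 libraries, edgeR, adjusted p = 1.89e-12) and Sirup (-0.92, 2 of 2, edgeR, adjusted p = 4.49e-09). At day 3 fok also fell in MTF-1 (-0.89) and alphaCOP (-1.75) and Sirup in E2f1 (-0.86). The sima and tgo profiles correlated at r = 0.107 across genes, rank 13 of 1035 pairs of targets.

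Zfh1, srp and pnr act in blood and mesoderm development. In zfh1 the odd-skipped family gene bowl (FBgn0004893, 2L 3771700 to 3784121) rose from 2.48 ± 1.31 to 225.4 ± 234.9 CPM (6.55 ± 0.45, 6 of 6 libraries, edgeR, adjusted p = 6.4e-17), more with dsRNA 2 (7.35 without dsRNA 1) than with dsRNA 1 (4.62 without dsRNA 2). The lipid enzyme Agpat2 rose from 5.12 ± 2.05 to 55.4 ± 14.7 (3.37 ± 0.33, 6 of 6, edgeR, adjusted p = 6.11e-13) and CG9168 by 2.73 ± 0.53 (6 of 6, edgeR, adjusted p = 0.000162). SPH93 (-2.05 ± 0.49), the phagocytosis receptor NimC4 (-1.998 ± 0.53) and CG18557 (-1.99 ± 0.45) fell most, in 6 of 6 libraries each (edgeR, adjusted p = 0.00301, 0.0128 and 0.00236). The latter pair was lost without dsRNA 2 (-1.21 and -1.46). In srp, a GATA factor, CG13795 fell from 50.7 ± 10.1 to 9.35 ± 3.13 CPM (-2.54 ± 0.30, 6 of 6, edgeR, adjusted p = 4.11e-09). CG42324 (FBgn0259224, 3L 3472447 to 3510895) fell from 138.0 ± 13.6 to 53.0 ± 5.74 (-1.37 ± 0.13, 6 of 6, edgeR, adjusted p = 1.98e-12). Tektin-A (3.00 ± 0.64), the carbonic anhydrase CAH1 (2.67 ± 0.60) and bab2 (0.97 ± 0.21) rose in 6 of 6 libraries (edgeR, adjusted p = 0.00228, 0.00396 and 0.00238). All 3 calls were lost without dsRNA 2 (1.84, 2.44 and 0.58). The integrin Itgbn fell by 1.95 ± 0.49 (6 of 6, edgeR, adjusted p = 0.0129), lost without dsRNA 1 (-1.68), dsRNA 2 (-2.15) or control well 2 (-1.75).

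In pnr, the second GATA factor, CG42324 rose to 305.4 ± 4.15 CPM (1.17 ± 0.10, 6 of 6, edgeR, adjusted p = 1.09e-15). CG3246 rose from 7.30 ± 1.56 to 47.1 ± 8.11 (2.73 ± 0.29, 6 of 6, edgeR, adjusted p = 1.84e-11). In srp CG3246 had 2 counts against 51 and was 11.7-fold lower (3.06 to 98.8), a call lost without dsRNA 1 (-3.15) or 2 (-3.59). Idgf2 fell by 1.20 ± 0.29 in pnr (6 of 6, edgeR, adjusted p = 0.0183), lost without dsRNA 1 (-1.47), dsRNA 2 (-0.96) or control well 5 (-1.16). All 5 genes changed in both srp and pnr moved in opposite directions (3 opposite in either split of the controls, 4 of 5 without the day-3 wells A2, C2 and E2). Fisher's exact test of the overlap, which ignores direction, gave adjusted p = 3.08e-05. In ct, a homeodomain factor with 4 changed genes, Kah rose from 192.2 to 397.2 ± 36.7 CPM (1.05 ± 0.16, 6 of 6, edgeR, adjusted p = 5.95e-05).

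SREBP is the activator of lipid synthesis genes. The fatty acid synthase FASN1 (FBgn0283427, 2L 3056598 to 3068177) fell in its knockdown from 4603 ± 548.0 to 329.9 ± 11.4 CPM (-3.81 ± 0.18, 6 of 6 libraries, edgeR, adjusted p = 8.6e-24). CG10383 fell from 267.6 ± 24.7 to 37.7 ± 11.7 (-2.99 ± 0.23, 6 of 6, edgeR, adjusted p = 2.12e-14). The phospholipid genes Pcyt1 (1268 to 599.1 CPM, -1.07, edgeR, adjusted p = 4.54e-06) and Pect (641.6 to 373.3 CPM, -0.78, edgeR, adjusted p = 8.73e-06) fell too, both in 6 of 6 libraries. Bdl, with 2 counts against 52, was 10.8-fold lower (2.85 to 91.6). Cyp28d1 (1.61 ± 0.34), shv (0.76 ± 0.12) and the autophagy adaptor ref(2)P (0.61 ± 0.15) rose most among genes higher in 6 of 6 libraries (edgeR, adjusted p = 0.00248, 4.19e-05 and 0.0133). The calls of bdl (-2.23), Cyp28d1 (0.88) and shv (0.46) were lost without dsRNA 2, and that of ref(2)P without dsRNA 1 (0.63) or 2 (0.60). Mondo changed 2 genes, its own included. Simulated changes at day 3 in SREBP, in genes with at least 5 CPM, were recovered at 76% when lowered by 1 log2 unit and 82% when raised by 1. They were drawn with the spread of the 3-day sums, not of single libraries.

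Among targets with 10 to 50 changed genes, ttk, a repressor of neural fate, raised the transmembrane gene kon on its knockdown from 5.61 ± 3.83 to 45.6 ± 35.6 CPM (3.21 ± 0.46, 6 of 6 libraries, edgeR, adjusted p = 7.88e-07). SPH93 rose from 14.8 ± 2.97 to 70.5 ± 43.9 (2.25 ± 0.26, 6 of 6, edgeR, adjusted p = 1.34e-09), and CG42324 fell (-0.60 ± 0.12, 6 of 6, edgeR, adjusted p = 0.000532, lost without dsRNA 2 at -0.56). Knockdown of Trl, the GAGA factor, lowered capu from 457.7 ± 61.6 to 204.1 ± 22.0 CPM (-1.15 ± 0.11, 6 of 6, edgeR, adjusted p = 5.37e-13). Zormin, a titin-like gene with 3 counts against 90, was 16.5-fold lower (5.46 to 81.4). Pih1D1 rose by 0.50 ± 0.07 in Trl (6 of 6, edgeR, adjusted p = 7.27e-07). Knockdown of dwg, an insulator factor, lowered Ppt2 from 19.8 ± 5.5 to 4.95 ± 1.34 CPM (-2.09 ± 0.36, 6 of 6, edgeR, adjusted p = 8.51e-05, lost without dsRNA 2 at -1.81). It raised CG6712 by 0.51 ± 0.13 (6 of 6, edgeR, adjusted p = 0.0334), a call lost without either dsRNA (0.63 and 0.41) or without control well 2 (0.51), 3 (0.49), 4 (0.46) or 5 (0.52). In Deaf1 Kah fell by 1.14 ± 0.21 (6 of 6, edgeR, adjusted p = 0.00453), lost without dsRNA 1 (-1.37) or 2 (-0.95).

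Gene lists fixed beforehand were tested in every knockdown, and the mitosis list in Myb stood furthest apart. Of its 14 members, Cks30A, the mitotic kinase aurB (288.7 to 146.6 CPM, -0.99 ± 0.15, 6 of 6 libraries, edgeR, adjusted p = 5.06e-06), the kinesin gene pav (667.2 to 355.0 CPM, -0.92 ± 0.08, 6 of 6, edgeR, adjusted p = 2.92e-14) and cana (-0.93, 6 of 6, edgeR, adjusted p = 4.39e-12) were the 4 that fell most. In all 11 fell over all genes and 11 adjusted over the list alone, and none rose (camera, adjusted p = 1.28e-27). In SREBP 3 of 7 fatty acid genes fell, FASN1, Pcyt1 and Pect (camera, adjusted p = 1.07e-08), also 3 adjusted over the list alone. The actin list fell in Jra and kay with 4 of 11 members each and none higher (camera, adjusted p = 2.69e-05 and 0.00143), or 6 lower each and 1 higher in Jra adjusted over the list alone. Its members were Arpc1 of the Arp2/3 complex (1890 to 1054 CPM in Jra, -0.84 ± 0.09, and to 1035 in kay, -0.87), capt (-0.47 and -0.74), Arpc5 (-0.51 and -0.62), Arpc2 in Jra (-0.28) and the profilin chic in kay (9436 to 6358 CPM, -0.57), each in 6 of 6 libraries. Arpc2 was lost in Jra without either dsRNA (-0.26 both) or without control well 1 (-0.25), 2 (-0.27) or 5 (-0.26), and capt in Jra without dsRNA 1 (-0.38). These 4 calls and the histone list in thread held with an estimated correlation between genes (camera, adjusted p = 0.000321 for Myb, 0.00455 for SREBP, 0.000888 for Jra, 0.0131 for kay and 0.0341 for thread). The other 36 of 41 calls did not.

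**Figure D4:**
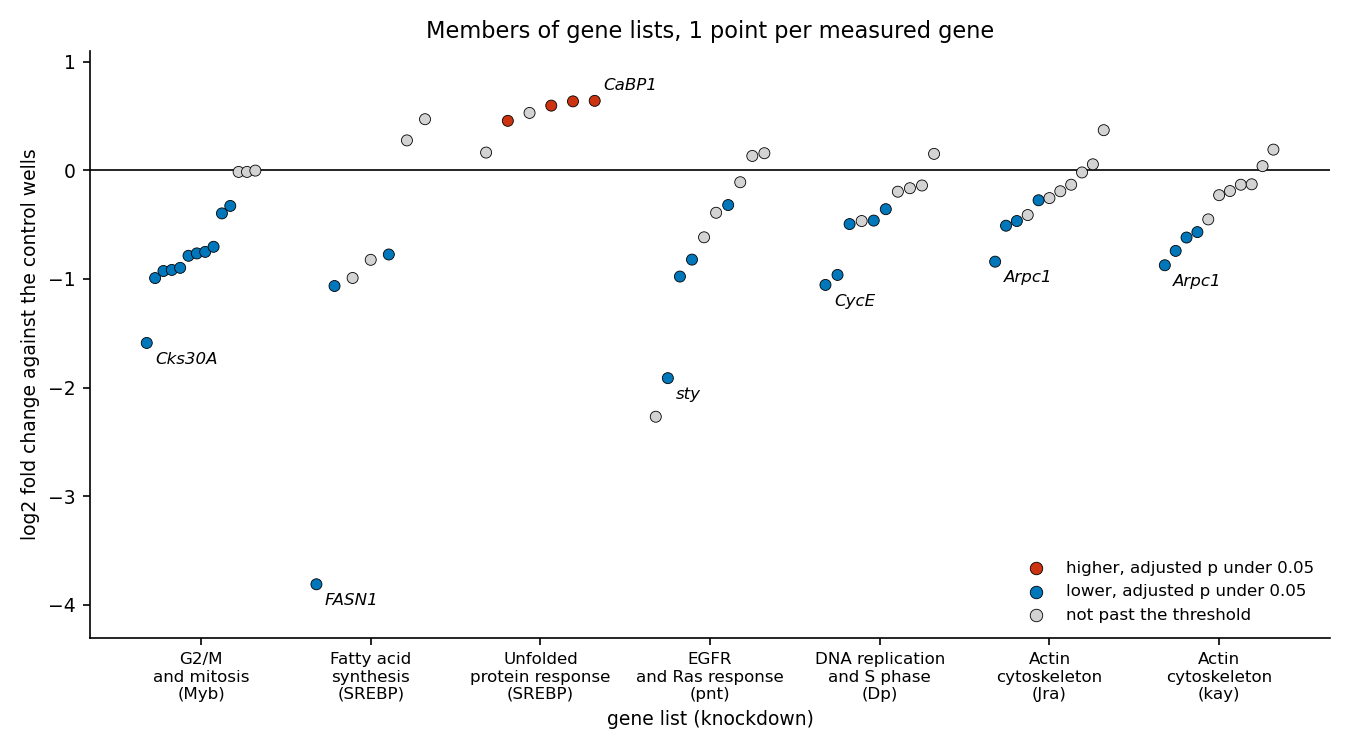
Log2 fold change over 3 days of each measured member (points) of 6 lists in the knockdowns for which they passed the threshold. Mitosis genes in Myb, fatty acid genes in SREBP, EGFR response genes in pnt and actin genes in Jra and kay have medians below 0 and unfolded protein response genes in SREBP a median above 0 under every scaling, while of the S-phase genes in Dp 1 of 10 lies above 0 under TMM and 5 under spike-in scaling.

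The following calls were lost. In SREBP the unfolded protein response list rose with 4 of 6 members, by both adjustments (camera, adjusted p = 9.63e-07, adjusted p = 0.146 with an estimated correlation). The chaperone CaBP1 rose by 0.64 (1193 to 1845 CPM, 5 of 6 libraries), Ero1L by 0.63 (4 of 6), Herp by 0.59 and Der-1 by 0.46 (4 of 6). All 4 calls were lost without dsRNA 2 (0.35, 0.27, 0.31 and 0.24). In pnt the EGFR list fell with 4 of 10, by both adjustments (camera, adjusted p = 2.82e-05, adjusted p = 0.119 with an estimated correlation). In Dp the S-phase list fell on the TMM scale with 5 of 10 and 7 adjusted over the list alone (camera, adjusted p = 0.000363, adjusted p = 0.632 with an estimated correlation). Its members were CycE, Psf1, the thymidylate synthase gene Ts (-0.50, 6 of 6, edgeR, adjusted p = 0.0457, lost without control well 1 at -0.51, 2 at -0.44 or 5 at -0.47 or dsRNA 2 at -0.32) and RfC3 (-0.46, 6 of 6, edgeR, adjusted p = 0.00873, lost without dsRNA 1 at -0.47 or 2 at -0.43). The list median moved from -0.41 to -0.02 under spike-in scaling. In zfh1 the hypoxia and glycolysis list rose with 3 of 5, by both adjustments (camera, adjusted p = 0.00422, adjusted p = 0.467 with an estimated correlation). Pgk rose by 0.53, Eno by 0.44 and the glucose transporter Glut1 by 2.98 (4 of 6 libraries). All 3 calls were lost without dsRNA 2 (0.43, 0.22 and 2.25) and Glut1 also without control well 2 (2.52). The hemocyte list rose in ttk with 2 of 16 members and 3 adjusted over the list alone (camera, adjusted p = 0.0368, adjusted p = 0.371 with an estimated correlation). The mitosis list was higher in E2f2 with 1 of 14, Cdk1 (0.49, 5 of 6 libraries, edgeR, adjusted p = 0.0331, lost without control well 3 at 0.46 or 4 at 0.43 or without dsRNA 1 at 0.43 or 2 at 0.54), and 5 adjusted over the list alone (camera, adjusted p = 0.000297). The S-phase list was higher in Myb with CycE (0.57) and RnrL (0.37, lost without dsRNA 1 at 0.32; camera, adjusted p = 0.00847).

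Ribosomal protein and histone lists gave 13 and 12 calls, mostly without single genes past the threshold. In pnt ribosomal protein genes fell with 8 of 20 members and 10 adjusted over the list alone (camera, adjusted p = 4.2e-06, adjusted p = 0.765 with an estimated correlation). The 4 that moved most were RpL30, which fell by 0.27, RpL28 by 0.26, RpL23A by 0.26 and RpS13 by 0.25, each lost without dsRNA 1 or 2. Without them RpL30 stood at -0.18 and -0.34, RpL28 at -0.14 and -0.37, RpL23A at -0.20 and -0.30, and RpS13 at -0.30 and -0.19. RpL30 was also lost without control well 2 (-0.25) or 4 (-0.25), and RpL28 without 3 (-0.23), 4 (-0.22) or 5 (-0.26). In SREBP the test and the median (-0.12) pointed down but the mean (0.00) did not (camera, adjusted p = 0.000297, adjusted p = 0.789 with an estimated correlation). In Dp histone genes fell with 5 of 111 members and 0 adjusted over the list alone (camera, adjusted p = 7.64e-06, adjusted p = 0.632 with an estimated correlation). The 4 copies that moved most held only 2 or 3 counts in Dp, against 27 to 35 in the control wells. The medians of ribosomal protein genes in pnt (-0.21) and of histone genes in Dp (-0.78) kept their sign under each scaling. Under spike-in scaling the median ribosomal protein change passed 0 in thread (0.17 to -2.26), Dp (-0.12 to 0.25), zfh1, Trf, Hsf, exd and Myb, and that of histones in thread (1.84 to -0.49), E2f2 (-0.26 to 0.15), Eip74EF and maf-S. The unfolded protein response list was called in alphaCOP (0 members, 2 adjusted over the list alone; camera, adjusted p = 0.0174, adjusted p = 0.789 with an estimated correlation), where its median went from 0.24 to -0.13 under spike-in scaling. It was called in mip120 with 2 of 6 members, CaBP1 (0.47, lost without dsRNA 1 at 0.43) and Der-1 (0.30, 4 of 6 libraries, lost without dsRNA 1 at 0.30 or 2 at 0.32 or control well 4 at 0.25 or 5 at 0.30), and 3 adjusted over the list alone (camera, adjusted p = 0.0255, adjusted p = 0.789 with an estimated correlation). The mitosis list was called in E2f1 (camera, adjusted p = 0.00308) and usp (0.00042) and the immune list in Mef2 (0.0491), all with 0 members past the threshold over all genes, at p = 0.789, 0.789 and 0.382 with an estimated correlation.

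The remaining lists passed in no knockdown. Their smallest camera adjusted p was 0.0615 for DNA damage (in Trf), 0.0689 for muscle (in h), 0.0712 for germline (in SREBP), 0.0831 for neuronal genes (in ttk), and 0.0856 for the secretory pathway (in Mondo). It was 0.101 for epithelial genes (in tsh), 0.191 for insulin and TOR signalling (in ap) and 0.356 for ecdysone (in ftz-f1). Of 56 tests of a list in a target it was chosen for, 10 passed, 2 of them with an estimated correlation. Hypoxia and glycolysis in sima (camera, adjusted p = 0.95, with a median of -0.06 against an upward test) and hemocyte genes in srp (0.409) were among those that did not. Of the small lists, metal response (1 gene measured), heat shock (1), JNK (4), circadian clock (4), Hippo (3), oxidative stress (3), Notch (3), JAK/STAT (3) and RNAi (2) gave few calls in the targets they were chosen for. Traf4 rose in kay (0.82, 6 of 6 libraries, edgeR, adjusted p = 3.04e-05) and the receptor Pvr in Jra (0.39, 6 of 6, edgeR, adjusted p = 0.0337), 2 of 8 values for JNK. The Notch response gene emc fell in da (-0.95, 6 of 6, edgeR, adjusted p = 7.97e-07), 1 of 9. Circadian genes had 1 of 12 (vri itself) and 2 adjusted over the list alone, with jet in vri (-0.63, 4 of 6 libraries). JAK/STAT had 0 of 6, with Socs36E in Jra (-0.39, 6 of 6) past it adjusted over the list alone (0.0352, against 0.165 over all genes by edgeR). Hsp83 in Hsf was lower over 3 days (-0.42, 6 of 6, edgeR, adjusted p = 0.477, and 0.00295 adjusted over the list alone), and ZnT63C in MTF-1 showed no change (-0.01, edgeR, adjusted p = 1). Hippo and oxidative stress genes had 0 of 3 each, RNAi genes were called in no target, and no apoptosis or transposon-derived gene was measured.

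Among genes changed in several knockdowns, the adenylyl cyclase gene Ac3 (FBgn0023416, 2L 21632587 to 21647964) was lower in 7 targets (Dp, E2f2, kay, sima, SREBP, z and zfh1), by 0.64 ± 0.09 in Dp (6 of 6 libraries, edgeR, adjusted p = 3.6e-08). Its other calls were lost without dsRNA 2 in kay (-0.22), SREBP (-0.41) and z (-0.26) and without dsRNA 1 or 2 in E2f2 (-0.37 and -0.40), sima (-0.35 and -0.26) and zfh1 (-0.29 and -0.36). With FPKM the last 3 lay above 0 (0.01, 0.05 and 0.07). Btk (FBgn0003502) was higher in 6 and lower in 1, CG42324 higher in 2 and lower in 5, Kah and zormin (FBgn0052311) higher in 3 and lower in 4. CG9331 and SPH93 were higher in 5 and lower in 1, Npc2a higher in 3 and lower in 3, Alg2 higher in 1 and lower in 4, and capu lower in 5. Zormin rose from 22.3 ± 3.23 to 117.1 ± 35.0 CPM in pnt (2.44 ± 0.25, 5 of 6, edgeR, adjusted p = 2.13e-11) and fell by 1.92 ± 0.44 in kay (6 of 6, edgeR, adjusted p = 0.000628). All targets share 5 control wells, so a chance low or high control value enters each of these counts. Of 229 named results that passed the threshold or belong to a target's own transcript, 113 lost the threshold when a control well or a dsRNA was left out, 68 of them only through a dsRNA.

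Thread encodes the caspase inhibitor Diap1, and its knockdown, the cell-death control in a single well, changed 593 genes (270 higher, 323 lower), 371 of them on 1 side of the control in all 3 libraries. The sum over days is mostly the day-1 library (352065 used counts, then 21513 and 8047), while the control sums mix the days, so changes of the control wells with time enter these values. Means of the per-day contrasts gave 168 genes. Histone genes rose most on the TMM scale, though 39 of 111 copies lay above 0 under spike-in scaling. His3:CG33833 rose from 1.74 ± 1.22 to 23.1 CPM (3.87 ± 0.76, 3 of 3 libraries, edgeR, adjusted p = 5.57e-05), His4:CG33877 from 2.38 ± 1.06 to 28.2 (3.43 ± 0.68, 3 of 3, edgeR, adjusted p = 5.54e-05) and 8 others by 2.42 to 3.85. Of 111 histone copies 48 were higher and none lower, 56 adjusted over the list alone, and 98 lay above 0 under TMM against 39 under spike-in scaling. Genes with 0 counts were lower at least 3.32-fold (CG31689, 187 control counts), 1.88-fold (lncRNA:CR44197), 1.76-fold (rho-5 and vkg), 1.46-fold (Patsas) and 1.24-fold (Itgbn, lost without control well 2 at -6.86, and at -7.03 and -7.05 without dsRNA 1 or 2 of the other targets, which moves the shared spread). By voom with a random block Patsas (0.16) and Itgbn (0.36) lay above 0. CG4970 was 17.3-fold lower (3.09 to 686), lncRNA:CR46259 14.1-fold (2.50 to 558) and CG11634 6.75-fold (2.29 to 32.9), and fok fell from 1140.0 to 84.7 CPM (-3.76 ± 0.99, 3 of 3, edgeR, adjusted p = 0.0036). The share of higher genes moved from 45.5% to 58.2% with DESeq2 size factors, to 60.1% by DESeq2 and to 0.1% with spike-in scaling, so directions in thread hold only relative to the median gene. Simulated genes with at least 5 CPM, changed by 1 log2 unit in thread, were recovered at 66% when lowered and 62% when raised.

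By day, the 46 targets together gave 410 calls at day 1 (145 higher, 265 lower), 1324 at day 2 (644 higher, 680 lower) and 2415 at day 3 (1274 higher, 1141 lower). By voom these were 1988, 861 and 4453, and 2 control libraries of day 1 were nearly empty, so no course over the days follows from them. Kay went from 52 to 313 and 546, Dp from 20 to 134 and 233 (147 at day 3 without wells A2, C2 and E2), SREBP from 10 to 33 and 213, and mip120 from 0 (edgeR; 59 genes at an unadjusted p under 0.05, 0 by voom) to 43 and 219. The target pnt had its highest count at day 2 (29, 206 and 136). Thread had 461, 72 and 7, in single libraries of 352065, 21513 and 8047 used counts, so these counts are no time course. The difference of a response between day 3 and day 1 passed the test for 484 genes over the targets, 151 of them in kay, 85 in SREBP and 24 in mip120 (47 without wells A2, C2 and E2 of day 3); of these 484, 49.0% were higher at day 3, and 61.0% with DESeq2 size factors. In thread 0 genes differed by edgeR, with 128 at an unadjusted p under 0.05 and 1551 by voom. Among the targets' own transcripts the difference was significant for E2f2 (-1.87), Trf (-3.35) and da (-1.25) in their own knockdowns, in da through dsRNA 1 alone. Day and plate are the same here, and depth differed between days, so the counts of different days are not counts of equal power.

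**Figure D5:**
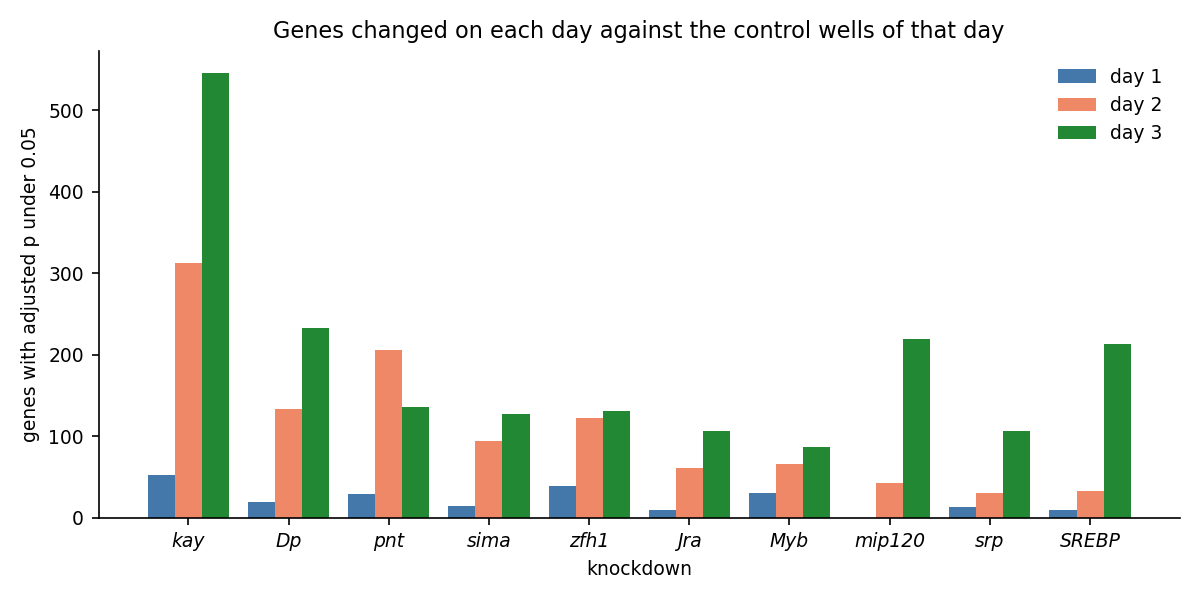
Number of changed genes at days 1, 2 and 3 (bars) for the 10 targets with the most changed genes. Kay rose from 52 to 546 and SREBP from 10 to 213, while pnt was highest at day 2 with 206.

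Control wells changed with time on the plate. From day 1 to day 3 the clock gene tim rose from 2.61 to 32.7 CPM, pooled over the wells of a day (3.52 ± 0.50, edgeR, adjusted p = 1.99e-10, n = 5 against 5). CG17549 rose from 6.25 to 41.9, pooled likewise (2.71 ± 0.38, edgeR, adjusted p = 6.48e-11). PLCXD rose by 2.45 ± 0.51 and Cda5 by 2.29 ± 0.46. The chaperone Hsp83 (FBgn0001233, 3L 3192969 to 3197059) fell from 15110.0 ± 2748 to 8468 ± 574.7 CPM (-0.89 ± 0.11, edgeR, adjusted p = 1.93e-14). The translation factor eEF1delta fell from 1761 ± 324.7 to 966.2 ± 38.1 (-0.91 ± 0.10, edgeR, adjusted p = 4.4e-16) and the chaperonin subunit CCT4 from 1871 ± 215.2 to 1175 ± 112.3 (-0.74 ± 0.10, edgeR, adjusted p = 5.11e-11). L(2)34Fd, CG34132, CG1416, Naglu, dbe, SerRS and Prosalpha6 fell by 0.98, 0.90, 0.75, 0.73, 0.69, 0.66 and 0.60. PLCXD and Cda5 had edgeR adjusted p = 3.84e-05 and 1.29e-05. These genes were named only if the 5 wells of day 1 and of day 3 did not overlap, so the separation is no further support. At day 1, 2 of the wells were nearly empty and read 0 for low genes. For the 4 risers the condition thus rests on the other 3 wells.

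Further risers had 1 to 3 counts at day 1: the ratios were 16.3 for kon (2.68 to 671), 15.0 for CG5050 (2.44 to 620), 11.8 for His2A:CG33838 (1.86 to 490), 10.5 for His2A:CG33859 (1.63 to 439), 5.89 for CG17493 (1.81 to 30.3) and 5.23 for Spn31A (1.59 to 27.1). Their calls were lost without 1 of the control wells, as for kon without well 5 (3.05), CG5050 without well 1 (3.05), His2A:CG33838 without well 2 (2.77) or 5 (2.35), and CG17493 without well 1 (2.14) or 2 (1.84). The same held for Spn31A without well 2 (2.33), 3 (1.93) or 5 (2.00), and His2A:CG33859 without well 1 (2.67), 2 (2.44), 3 (2.82) or 5 (4.52). In all 484 genes changed between day 3 and day 1 (246 higher, 238 lower) and 142 between day 2 and day 1 (71 each way), and 147 and 51 of them did not overlap, or 393 and 130 with the 3 deeper libraries of day 1 alone. Without control well 2 the first count was 319, and the second was 75, 92 and 84 without control well 1, 2 and 5. Simulated changes of 1 log2 unit in genes with at least 5 CPM were recovered at 92% (lowered) and 94% (raised). They were drawn with the spread of the 3-day sums, not of single libraries. Any difference between plates is part of the changes between days.

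Both dsRNAs of a target were compared to see whether they changed the same genes. The profiles of Dp (r = 0.676 across genes), mip120 (0.648), kay (0.613), Myb (0.572) and sima (0.51) agreed most, and that of tgo least (0.099), though with split controls Pdp1 (-0.044) and others stood below tgo (-0.004). The mean r over 44 targets was 0.297, against 0.193 for dsRNAs of different targets (permutation test, one-sided, p = 1e-05, the smallest that 100000 resamples can give). Simulated unchanged wells gave 0.205 through the shared controls, with a covariance of 0.0251 against 0.0497 observed. With the control wells split between the dsRNAs the mean r was 0.098 against 0.007 for different targets and -0.003 in the simulation (permutation p = 1e-05), and the covariance was 0.0232 against -0.000451. At day 1 alone the mean r was 0.801 but that of different targets 0.795 (permutation p = 0.002), where 2 control libraries were nearly empty. The correlations are across genes, which are not independent replicates.

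Known partners were compared in the same way on profiles from which the mean of all knockdowns was removed. Jra and kay had the highest r of 1035 pairs (0.32), followed by E2f2 and Dp (0.297) and E2f2 and mip120 (0.294), while E2f2 and Myb had the lowest (-0.254, rank 1035). E2f1 and Dp stood at 0.098 (rank 21), Myb and mip120 at -0.045 and srp and pnr at -0.066. The 20 pairs fixed beforehand had a mean r of 0.043 against -0.02 for all pairs (permutation test, one-sided, p = 7e-05, highest permuted mean 0.065). The 3 highest carried it, with a mean of 0.304, and the other 17 stood at -0.003. On fold changes against the control wells, which all pairs share, it was 0.337 against 0.293 (permutation p = 0.0023). Among pairs not fixed beforehand, kay and sima stood at rank 4 with 0.258, chosen after the values were seen.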

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

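All tests of explanations in this part were chosen after the results were seen, except the comparisons of the control days with other splits of the same libraries and the tests of differences between days.

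In E2f2 the own transcript was lower at day 3 than at day 1 relative to the controls (difference of log2 fold changes -1.87), and in Trf (-3.35) and da (-1.25) it moved the same way. In da only dsRNA 1 did so (213% to 112% of the control level), while dsRNA 2 went from 17.9% to 20.5%. E2f2 fell further with time in Dp (-0.94), but stood at -0.10 without wells A2, C2 and E2 of day 3 (edgeR, adjusted p = 1). A gene is said to fall or rise further if its log2 fold change was lower or higher at day 3 than at day 1, whatever its day-1 value. Of the AP-1 genes, Kah (-1.71) and Arpc1 (-0.86) fell further in Jra, and Apoltp (1.25) and Pxn (0.88) rose further. In kay Npc2a (-1.22), capu (-1.12) and Ac3 (-0.80) fell further and CG9331 (0.77) rose. In SREBP Ero1L (1.51), shv (1.29), Der-1 (1.13), CaBP1 (1.12), Herp (1.08) and ref(2)P (0.76) stood higher at day 3 than at day 1. At day 1 Ero1L (0.05), Der-1 (-0.14), CaBP1 (0.14) and Herp (0.06) had not passed the threshold. FASN1 (-0.89) fell further. CG13084 rose further in mip120 (3.33), fok fell further in sima (-1.75), and CG42324 (-1.50) and capu (-0.96) fell further in Trl. In all 484 genes over the 46 targets differed between these days, 151 in kay and 85 in SREBP (edgeR). Day and plate are the same in this design.

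Within the 5 control wells, 1 well lay far from the others, with a gap to its nearest neighbour of over 0.71 of the whole range, for 22 of 180 groups of 5 values, where chance gives about 1 in 20. In sums over 3 days these were Agpat2 (gap 0.719 of the range), CG9168 (0.715), Pvf3 (0.71), CG32982 (0.809), Fam92 (0.75), Cks30A (0.751), CG13084 (0.732), kon (0.872), alphaCOP (0.878), CaBP1 (0.745), Herp (0.749), Arpc5 (0.743) and RfC3 (0.925). At day 1 they were kon, CG5050, His2A:CG33838 and His2A:CG33859 (each 1, because 4 of the 5 wells held no count), Hsp83 (0.969), CCT4 (0.799) and dbe (0.885), and at day 3 Spn31A (0.733) and dbe (0.741). The labels do not say which of the 5 wells got LacZ, GFP or no dsRNA.

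The spike-in share of counts was 4.71%, 15.8% and 26.8% in the thread wells at days 1, 2 and 3, against 0.706% to 1.91%, 0.771% to 2.12% and 0.521% to 1.22% in the control wells. The well of E2f1 dsRNA 1 at day 3 stood at 8.57%.

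At day 3, 3 wells of plate column 2 had a low transcript of the target of a neighbouring well. The alphaCOP transcript stood at 239.7 CPM in control well 3 (E2) and at 214.2 in Dp dsRNA 2 (C2), on both sides of the alphaCOP well (D2, 369.4), against a median of 1503. E2f2 stood at 27.0 CPM in C2 and 85.5 in Jra dsRNA 1 (A2), on both sides of E2f2 dsRNA 2 (B2, 57.2), against 258.9. Among 10 transcripts in 28 comparisons by day, 5 libraries of other targets were under 40% of the median, and these 4 lay next to a well of that target. In Jra at day 3 qtc (3.13) and CG4213 (2.49), which rose in E2f2, stood at 0.82 and 0.91 without wells A2, C2 and E2. The 3 libraries were kept, and the target transcripts outside the used part give no such check for other wells. The cause was not tested.

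The change of the control wells with time was set against other splits of the libraries. In a fit of the 10 libraries alone 224 genes differed between day 2 and day 1 and 520 between day 3 and day 1. Of 100 splits of the same libraries 1, the real one, gave as many in each case, and the highest others gave 118 and 188. Chance can be excluded, while a difference between plates remains part of both counts.

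Histone genes made up 0.163%, 0.284% and 0.298% of the used counts in the thread wells at days 1 to 3, against a median of 0.0364% (0.0205% to 0.0762%) in 272 libraries with at least 100000 used counts. Low depth is excluded as the cause, since 13 other libraries under 100000 used counts had a median of 0.0294% and at most 0.0933%. A smaller amount of poly(A) RNA per well, which might let histone transcripts make up more of a library, stays open. The histone share followed the spike-in share only weakly in the other libraries (Spearman 0.127, Pearson 0.153, permutation p = 0.0359), but none of those libraries had a spike-in share above 2.9%. Loss of cells after knockdown of a caspase inhibitor is a biological explanation that the design names, and it was not tested.

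Trf, da with dsRNA 1 and Hr39 with dsRNA 2 had an own transcript above the control level at day 1. Mislabelled wells are excluded as the whole cause, since these 3 dsRNAs, out of 18 ranked, had their own target's transcript at its highest level of the day-1 libraries, which a swapped well would give only by chance. Sequence of the dsRNA itself carried into the library could raise the count and stays open. The excess fell from day 1 to day 3 in 3 of 3 wells, but the counts of the gene opposite da, which might take up the second strand, were 0 in the da dsRNA 1 wells out of 25 over all libraries, too few to decide. A true rise of the transcript was not tested.

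On 2R, 3R, X and the rest of 3L, 20.5% of the housekeeping genes had at least 1000 counts over all libraries, against 95.5% in the used part of 2L and 3L and 2 of 4 on chromosome 4. Low sequencing depth is excluded as the cause, since it would lower genes everywhere. Counting against gene positions of another genome build is a candidate explanation that stays open. Shifting the gene positions on 2R by 4112700 bp gave a score of 1.344, the mean log10 count at the housekeeping genes, where the highest of 20 random scans was 1.06 and no shift gave 1.176. On 3R a shift by 4172900 bp gave 1.257, against 1.081 in the random scans and 1.019 with no shift. On 2L the score was 5.057 with no shift, against 1.833. With the genes of an arm in 2 sets, the best shifts of the sets were 19450 bp apart on 2R and 16600 bp on 3R. The bound first set for that distance, 1000 bp, was missed. With no shift the score on 2R already passed that of the random scans, and both shifted scores stayed far below that of 2L, so the test does not decide.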

How the results depend on the processing

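The alternatives with all genes of the count tables, without libraries under 100000 used counts and without wells A2, C2 and E2 of day 3 were chosen after the data were seen, and all others before. The 1894 calls over 46 targets were also made at 94.7% with DESeq2 size factors, 91.1% by DESeq2, 87.5% without a filter, 88% as means of days, 81.8% by voom with a random block, and 85.1% with plate row. The shares were 94.2% without libraries under 100000 counts, 86.8% without the 3 wells and 91.3% with all genes, but at 38.5% with FPKM, 35.7% without libraries under 1000000 gene counts and 15.1% with spike-in scaling, and 0 in the opposite direction. Of 4207 values of named genes 3424 kept their direction and side of the threshold, 755 passed it no longer, 5 passed it newly and 23 reversed. The cause of each change below was not tested unless given.

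Spike-in scaling gave a sum of 294 calls, 1 own transcript, 1 target with 100 or more changed genes, 1650 for thread, 41 for kay, 130 for Dp, 12 for pnt, 6 for sima, 24 for zfh1, 5 for Jra, 14 for Myb, 16 for mip120, 4 for srp and 2 for SREBP. Without libraries under 1000000 gene counts, which leaves fewer samples, the sum was 848, with 2 targets of 100 or more, 184 for kay, 75 for pnt, 39 for sima, 1 for zfh1, 0 for Jra (edgeR), 41 for Myb, 48 for mip120 and 5 for srp. E2f1 could not be fitted. FPKM gave 4 own transcripts, 268 for kay, 431 for pnt, 28 for sima, 52 for Jra, 36 for Myb, 55 for mip120, 26 for srp and 27 for SREBP. Means of days gave a sum of 3274, 10 targets of 100 or more, 168 for thread, 229 for sima, 258 for zfh1, 147 for Myb, 208 for mip120, 134 for srp and 149 for SREBP. All genes of the tables, more genes tested, gave a sum of 3816, 10 targets of 100 or more, 1134 for thread, 1282 for kay, 464 for Dp, 478 for pnt, 2.9e+02 for sima (rounded), 306 for zfh1, 190 for Jra, 156 each for Myb and mip120, 96 for srp and 110 for SREBP. No filter gave 10 targets of 100 or more, 168 for mip120, 103 for srp and 121 for SREBP. Without the 3 wells the sum was 1782, with 194 for Dp and 92 for Jra. Voom with a random block gave 1914 for thread, 202 for zfh1, 170 for mip120 and 113 for SREBP.

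Leaving out 1 control well or dsRNA gave 4 to 7 own transcripts, a sum of 883 to 1839, 2 to 7 targets of 100 or more, 300 to 527 for kay, and 110 to 284 for Dp. They gave 48 to 248 for pnt, 19 to 162 for sima, 16 to 160 for zfh1, 39 to 102 for Jra, 55 to 96 for Myb, 32 to 104 for mip120, 6 to 91 for srp, 12 to 57 for SREBP, 75 to 153 for the control wells between days 2 and 1 and 319 to 438 between days 3 and 1. With 1 dsRNA the lone well is assumed to vary like the others.

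In single days voom gave 1988 calls at day 1, 861 at day 2 and 4453 at day 3, 1810 for the difference between days 3 and 1 and 1447 for the control wells between them, and a fit of day 1 alone gave 264. The replicate numbers were not taken to pair the samples, as 4 of 15 correlations of control wells over days were over 0.1. All 4 were among the 5 between days 2 and 3 (the fifth 0.003), and the rest involve day 1, where 2 control libraries were nearly empty. The replicate block gave 3598 calls for the difference between days, 1568 for the control wells between days 2 and 1 and 1949 between days 3 and 1. On simulated counts this fit made 737 and 330 false calls, and 11 and 3 without libraries under 100000 counts. This shows part of the cause, as without them it still gave 1414 for the difference between days. Of 41 list calls 5 held with an estimated correlation and voom gave 131.

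Reversed values were, in thread by voom with a random block, Patsas (0.157) and Itgbn (0.361), da in the da knockdown without dsRNA 2 (0.489, range from -2.114), Hr39 in the Hr39 knockdown without dsRNA 2 (-0.214, range to 0.62) and without libraries under 1000000 gene counts (-0.224). With FPKM they were Ac3 in E2f2 (0.01), sima (0.046) and zfh1 (0.066), capu in Jra (0.178), Alg2 in pnt (-0.09), Npc2a in srp (0.194) and zfh1 (0.206) and Hr39 in pnt (0.531), with spike-in scaling Ac3 in E2f2 (0.026) and aop in Dp (0.138), without libraries under 1000000 gene counts Alg2 (0.042) and Arpc2 (0.074) in Jra and SPH93 in pnt (-0.526), and with the replicate block kon (-0.038), CG5050 (-0.048), His2A:CG33838 (-0.373), His2A:CG33859 (-0.399) and Spn31A (-0.037) in the control wells. Depth limits genes under about 5 CPM, whose ratios rest on few counts, and day 1, where 2 control libraries were nearly empty.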

Other observations

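The genes in this part were chosen after their values were seen, each value at day 3 is from 2 libraries that lay on the same side of the pooled control wells, and no explanation of them was tested.

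The following values are from day 3 alone. In Hsf, the heat shock factor, Hsp83 fell from 8565 to 3660 CPM (-1.20 ± 0.14, log2 ± SE, edgeR, adjusted p = 1.67e-13), and its co-chaperone Stip1 from 2301 to 1142 (-0.999 ± 0.14, edgeR, adjusted p = 2.99e-10). The translation repressor Thor fell from 532.3 to 287.9 (-0.98, edgeR, adjusted p = 1.42e-09). In tgo fok fell from 1530.0 to 658.4 CPM (-1.05 ± 0.13, edgeR, adjusted p = 1.89e-12) and Sirup from 3231 to 1593 (-0.92 ± 0.13, edgeR, adjusted p = 4.49e-09). In Mondo cbt fell from 772.2 to 364.0 CPM (-1.07, edgeR, adjusted p = 6.92e-13).

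In E2f2 at day 3 qtc rose from 2.04 to 84.3 CPM (5.22, edgeR, adjusted p = 2.47e-16) and CG4213 from 5.79 to 95.5 (4.01, edgeR, adjusted p = 3.33e-16). The carbon dioxide receptor gene Gr63a, with 34 counts against 3, was 33.8-fold higher in E2f2 (10.6 to 172) and 42-fold in Dp (13.7 to 210), and CG15130, with 0 control counts, was at least 31.7-fold higher in Dp, 20.9-fold in E2f2 and 10.8-fold in mip120. Of the Dp libraries, 1 of 2 also had little E2f2 transcript and lay next to a well of E2f2 dsRNA. In ttk CG42784 rose from 39.2 to 491.7 CPM (3.62 ± 0.18, edgeR, adjusted p = 3.02e-81) and miple1 from 7.50 to 150.2 (4.28 ± 0.37, edgeR, adjusted p = 1.26e-27), and both had responded less at day 1 (differences 3.36 and 4.31, edgeR, adjusted p = 3.26e-13 and 0.000113). In Deaf1 robo2 fell from 238.5 to 78.9 CPM (-1.56, edgeR, adjusted p = 4.83e-13), and in Trl the glutamine synthetase gene Gs1 from 222.2 to 71.9 (-1.61, edgeR, adjusted p = 9.72e-18). In SREBP the ligand gene daw stood at 884.3 CPM at day 3 against 270.2 in the controls, and its response exceeded that of day 1 (difference 1.67, edgeR, adjusted p = 1.76e-11).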
